A study of Drosophila melanogaster with 6 samples.

How the data were processed

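Eye-antennal imaginal discs of Drosophila melanogaster were profiled at 5 and 11 days after egg laying, with 3 libraries per day, all reared at 25 °C. Libraries were made from polyadenylated RNA with a QuantSeq forward 3′ kit, per the labels' protocols, so that a transcript yields tags near its 3′ end. The values are whole-number read counts per gene, not normalized, as deposited by the authors, with 1 column per library. FastQC, cutadapt and STAR 2.6.1d and the genome build dm6 are named per the submitters' processing notes; the annotation, the counting program, its strand setting and its treatment of reads with several matches are not given in the sources used here, so that overlapping genes, antisense partners, near-identical paralogs and repeated sequences are uncertain. Samples were grouped by the time point in the labels, and no column was left unmapped.

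Gene symbols were used as the table gives them. Of 16727 genes, 12512 matched a current symbol and 3996 a RefSeq synonym of 1 gene, and 219 were not matched; 16508 had 1 locus in the Ensembl annotation of assembly release 6, the assembly that dm6 names, from which coordinates (1-based) and transcript lengths were taken. Transcript length was the median over a gene's annotated transcripts, and 98.6% of the tested genes had one.

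The counts were filtered with filterByExpr, scaled with TMM and tested with the quasi-likelihood test of edgeR 4.0.16 with robust shrinkage (R 4.3.3), day 11 over day 5, two-sided, with Benjamini-Hochberg adjustment over the 8010 genes tested and a threshold of 0.05; the common biological coefficient of variation was 0.211. CPM are TMM-scaled. SE and 95% intervals come from the same fit. With total counts of 6542782 to 9049513, 3 counts in a library stand for 0.332 to 0.459 CPM before TMM scaling; this floor covers counting error only, while the intervals also include the spread between libraries. Nothing in the labels says that the libraries of a day came from separate cultures, so p-values measure the spread between these samples, which may be technical in part. An exact permutation test of 3 against 3 libraries cannot give a p below 0.1. Replicates differed by more than sampling noise: the chi-square of counts per degree of freedom was 9.10 to 100.6 between libraries of the same day, so no library was counted as a duplicate.

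Before the data were examined, 42 gene lists were fixed from textbook knowledge of the tissue, its growth and the other cell types a dissection could hold; 7 list members were not found in the table. Lists were tested with camera of limma 3.58.1 on log-CPM (prior count 2) with a preset correlation of 0.01 and adjustment over the 42 lists. Of these, 17 were called, 0 with an estimated correlation and 20 by fry's directional p, which asks whether a list's genes move one way and does not compare them with other genes; fry's mixed p called 41. Members were counted at the threshold over all genes tested and again adjusted over the list alone. Named genes followed a rule fixed at the same time: the 6 largest rises and 6 largest falls among called genes with a mean of at least 20 CPM and no overlap between days, the Yorkie target genes, and the members with the smallest p, of at least 5 CPM, in the called lists and the lists of other cell types. EcR, yki and wts were named outside this rule, after their values were seen.

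The steps were tested on simulated counts drawn from the real means, dispersions and library sizes for the comparison of the days, with 200 changed genes: of the 2-fold changes 55.7% and of the 4-fold changes 92.9% were recovered among 7882 genes fitted, all in the right direction, and 12 of 157 calls were false. Far fewer genes changed there than the 2965 called in the real comparison, so these rates need not hold for it. Of 100 lists of unchanged genes, 1% had a camera p below 0.05 with the preset correlation, 0% with an estimated one and 4% a fry p below it; the simulated genes were independent of each other, which real list members are not. Alternatives were other scalings (DESeq2 1.42.0 size factors, upper quartile, total counts), no low-count filter, a filter of at least 5 CPM in 3 libraries, the DESeq2 Wald test, limma-voom, no robust shrinkage, a replicate block, and each library left out in turn.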

Results

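Messenger RNA was measured by 3′ tag sequencing in eye-antennal imaginal discs, the larval tissue from which the fly's eye, antenna and head capsule form. The Drosophila larvae, of genotype y w, fed on yeast that cannot make the sterols needed for moulting hormone and therefore did not pupate. Discs were taken 5 days after egg laying, when the tissue was still growing, and 11 days after egg laying, when growth had ended at the normal size. Each day was represented by 3 libraries, each from at least 30 discs. The libraries held 6542782 to 7950251 counts at day 5 and 7670180 to 9049513 at day 11. The table lists 16727 genes, of which 12816 had a count in any library. The comparison of the days asks which transcripts differ between a growing disc and a disc that has stopped growing. The days also differ in the age of the larvae and their time on this food. With no other group, effects of these cannot be told apart from the end of growth. The genes of first interest are the targets of Yorkie, the growth-promoting transcription coactivator that the Hippo pathway restrains.

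The libraries separated by day. The first principal component of log-CPM held 68.4% of the variance and parted the 3 day 5 libraries from the 3 day 11 libraries. Pearson correlations across genes, which are not independent replicates, were 0.954 to 0.973 between libraries of the same day and 0.867 to 0.902 between libraries of different days. A pair of short non-coding RNAs on chromosome X, CR40469 and CR34335, took 16.6% ± 2.29 of all counts at day 5 and 35.6% ± 8.03 at day 11 (SD, n = 3 each). Their share was 26.3% in day 11 replicate 1 and 40.8% and 39.6% in the other day 11 libraries. CR40469 rose (log2 fold change 1.49, SE 0.22, edgeR adjusted p = 0.00061), while CR34335 differed by 1.18 (SE 0.40) with adjusted p = 0.0659. How reads with several matches were counted is not given in the sources used here, so these values may include reads from other places in the genome.

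At day 11, 1533 genes were higher and 1432 lower than at day 5 among 8010 genes tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05). Of these, 832 rose and 534 fell at least 2-fold. Among called genes with a mean of at least 20 CPM and no overlap between the days, one of the largest rises was that of Eip93F, a transcription factor gene of the steroid hormone response. It went from 3.63 ± 1.82 to 308.2 ± 3.78 CPM (SD, n = 3 each), a log2 fold change of 6.41 (SE 0.29, edgeR adjusted p = 6.34e-07). Its annotated locus is chromosome 3R from 21949114 to 22014539. The cuticle protein gene Cpr100A rose from 0.787 ± 0.454 to 265.5 ± 129.7 CPM. The uncharacterised genes CG34247 and CG13053 rose from 5.78 ± 4.87 to 735.9 ± 92.6 CPM and from 0.552 ± 0.323 to 119.3 ± 2.14 CPM, and Scp2 rose from 0.723 ± 1.25 to 59.3 ± 10.2 CPM. The day 5 value of Scp2 came from replicate 2 alone, the others having no counts, so the size of its rise is uncertain (log2 fold change 6.27, and 11.8 without that library). CG15213 was close to the counting floor at day 5, with 0.128 ± 0.127 CPM, and reached 59.7 ± 23.9 CPM. The largest falls within the same limits were those of the non-coding RNA CR43283, CG14984, CG15765, the amino acid transporter gene mnd, the eye and leg determination gene dac and msd1. dac, on chromosome 2L from 16466512 to 16485998, went from 76.2 ± 8.20 to 12.9 ± 6.43 CPM (log2 fold change -2.54, SE 0.33, adjusted p = 0.00081). CG14984 went from 121.1 ± 19.3 to 15.5 ± 4.64 CPM. The fall of CR43283 (log2 fold change -3.90, SE 0.97, adjusted p = 0.0371) was past the threshold in 12 of 17 other settings, with adjusted p up to 0.138. The day 5 libraries held 96.86, 53.12 and 12.02 CPM of CR43283, now named lncRNA:cherub. Its log2 fold change was -3.18 without day 5 replicate 1. Medians of the brain and neuroblast list ran in the same order at day 5, at 9.39, 6.14 and 3.16 CPM. At day 11 they were 6.74, 7.69 and 8.72 CPM. Whether brain tissue carried over in the dissection adds to the fall of CR43283 was not tested. Scaling by total counts alone, which shifted the median log2 fold change of all genes by -0.27, gave 865 higher and 2207 lower genes. Rises were then 28.2% of the calls in place of 51.7%. The directions given here are relative to TMM scaling.

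The Yorkie target genes did not move one way. Of 12 listed genes 11 were tested, and 4 were higher and 2 lower at day 11. The counts were also 4 and 2 when adjusted over the list alone. Mer, dm (the Myc gene), th (the Diap1 inhibitor of cell death) and crb rose. Their log2 fold changes were 0.91 (SE 0.17, 95% interval 0.55 to 1.27), 0.57 (SE 0.12, 0.32 to 0.82), 0.55 (SE 0.12, 0.28 to 0.82) and 0.49 (SE 0.15, 0.17 to 0.81). The growth and polarity gene fj fell (log2 fold change -0.50, 95% interval -0.77 to -0.23), a call lost in 1 of 17 other settings. dally, a cell-surface proteoglycan gene, stood at -0.32 (95% interval -0.56 to -0.07, adjusted p = 0.0471), but lost its call in 12 of 17 other settings. The 5 others were not called. ex had a log2 fold change of 0.22 (95% interval -0.11 to 0.56), and CycE -0.27 (-0.63 to 0.10). The values were -0.27 (-0.61 to 0.06) for E2f, 0.12 (-0.22 to 0.45) for dlp and -0.06 (-0.45 to 0.33) for kibra. The list as a whole was not called by camera (adjusted p = 0.589; adjusted p = 0.775 with an estimated correlation). Its share of called members was 54.5%, against 37.0% among other genes (Fisher's exact test, two-sided p = 0.348). With 11 members the test could miss a difference of this size. The call of crb was lost in 5 of 17 other settings. Leaving out day 11 replicate 3 left 3 called members, and scaling by total counts left 3, with adjusted p of 0.216 for dm, 0.247 for th and 0.420 for crb. Leaving out day 11 replicate 1 gave 7, with falls of E2f (adjusted p = 0.00304) and CycE (adjusted p = 0.0270) called. With the transcript length trend removed 3 were higher and 3 lower, CycE among the lower (adjusted p = 0.0318), and the Yorkie target genes were still not called as a list (adjusted p = 0.808). For th and E2f no transcript length was found, so their values were not adjusted for length.

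**Figure D1:**
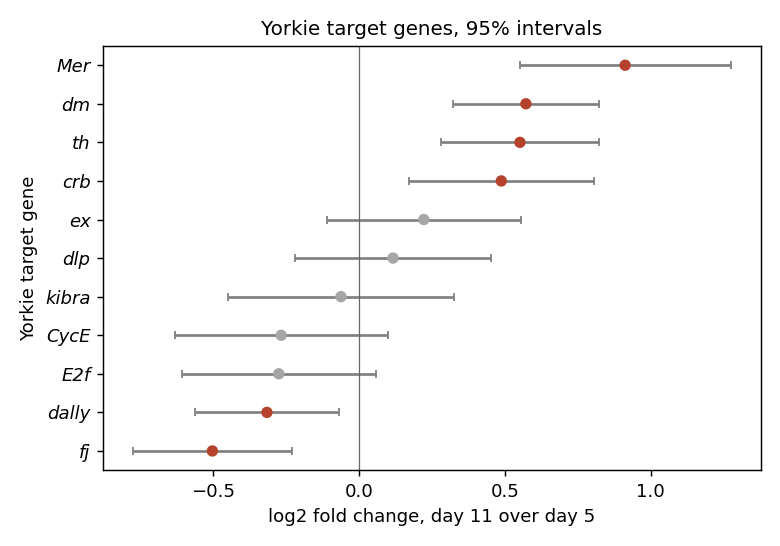
Log2 fold change, day 11 over day 5, of the 11 tested Yorkie target genes (points) with 95% intervals from the edgeR fit (bars, n = 3 libraries per day); red points have adjusted p below 0.05. Mer has the highest value, 0.91, and fj the lowest, -0.50, and the intervals of 5 genes cross 0.

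Among the Hippo pathway components, 8 of 37 tested genes rose and 1 fell (7 and 1 when adjusted over the list alone), and 28 were not called. With the transcript length trend removed 7 rose and 5 fell, and the median of Hippo pathway components went from 0.064 to -0.11. Rassf rose by a log2 fold change of 1.24 (SE 0.18, edgeR adjusted p = 0.00028) and Schip1, listed as CG5375, by 1.76 (SE 0.28), while the protocadherin gene ds fell by 0.70 (adjusted p = 0.0254), a call lost for ds in 2 of 17 other settings. yki itself had a log2 fold change of -0.35 (95% interval -0.75 to 0.04) and wts, the kinase that acts on it, 0.16 (-0.15 to 0.46), neither called. The list was not called by camera (adjusted p = 0.476). Of these genes, 4 also stand in the Yorkie target list.

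DNA replication genes fell together. Of 44 tested members 38 were lower at day 11 and none higher (40 and 0 when adjusted over the list alone). Their median log2 fold change was -1.29 (camera adjusted p = 1.23e-15; adjusted p = 0.144 with an estimated correlation). RnrS, a subunit gene of the enzyme that makes deoxyribonucleotides, went from 120.9 ± 7.31 to 24.0 ± 3.21 CPM (SD, n = 3 each; edgeR log2 fold change -2.34, SE 0.15, adjusted p = 9.39e-07). Claspin, a replication checkpoint gene, had a log2 fold change of -2.14 (SE 0.14) and PCNA, the sliding clamp gene, -1.62 (SE 0.14). Mitosis genes fell in part. Of 59 tested 22 were lower and 3 higher, also when adjusted over the list alone (camera adjusted p = 0.00012; adjusted p = 0.240 with an estimated correlation). The chromosomal passenger genes borr and ial (aurora B) had log2 fold changes of -1.78 (SE 0.17) and -1.40 (SE 0.14), and the mitotic kinase gene cdc2 -1.18. By contrast polo (0.44, SE 0.12), Incenp (0.55) and feo (0.36) rose. These rises lost their calls under total-count scaling, with adjusted p of 0.484, 0.324 and 0.704. In all, the calls of polo and Incenp were lost in 3 of 17 other settings each and that of feo in 5, most of them with a library left out. The number of called Mitosis members was 14 without day 5 replicate 2 and 15 without day 5 replicate 1.

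Genes for making ribosomes and for respiration fell in large part. Of 43 ribosome biogenesis genes 30 were lower and 2 higher (33 and 2 when adjusted over the list alone). Their median log2 fold change was -0.92 (camera adjusted p = 2.80e-09; adjusted p = 0.155 with an estimated correlation). The snoRNP gene nop5 had -1.66 (SE 0.13), hoip -1.91 and Nop60B -1.42. In the other direction Non1 (1.30) and Nop17l (0.75) rose. Of 85 cytosolic ribosomal protein genes 62 were lower and 1 higher (65 and 3 when adjusted over the list alone). Their median was -0.54 (camera adjusted p = 7.53e-11; adjusted p = 0.248 with an estimated correlation). RpL41 went from 23690 ± 3869 to 8572 ± 1454 CPM and RpS27A from 3119 ± 205.5 to 1449 ± 159.3 CPM. RpLP0-like, taken into the list by its symbol alone, had a log2 fold change of -1.91 at a mean of 17.6 CPM. RpS5b rose by 2.91. How the counting divided reads between RpS5b and its paralog is not given in the sources used here. Mitochondrial ribosomal protein genes were lower in 36 of 73 and higher in 2 (38 and 3 when adjusted over the list alone; adjusted p = 1.24e-07, and adjusted p = 0.301 with an estimated correlation). Here mRpL20 (-1.77), mRpS18A (-1.02) and mRpL54 (-1.10) fell, and mRpL45 (0.55) and mRpS28 (0.67) rose. The calls of mRpL45 and mRpS28 were each lost in 5 of 17 other settings and that of Nop17l in 6. Oxidative phosphorylation genes were lower in 43 of 67, and 46 when adjusted over the list alone (adjusted p = 2.49e-10; adjusted p = 0.337 with an estimated correlation). Among them were CoVb (-1.27), CG12859 (-1.18) and CG9603 (-1.15). Proteasome genes were lower in 20 of 31, and 26 when adjusted over the list alone (adjusted p = 5.56e-07; adjusted p = 0.248 with an estimated correlation). Among them were Prosalpha4 (-0.93), Prosalpha5 (-0.85) and Rpn11 (-0.81).

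Fold changes followed transcript length in the genes outside the lists too, from a median log2 fold change of -0.50 in 216 genes with transcripts up to 600 nt to 0.23 in 1113 genes with transcripts over 4000 nt. The median transcript length of the cytosolic ribosomal protein genes was 708.5 nt. With this trend removed, an alternative chosen after the data were seen, 26 cytosolic ribosomal protein genes were lower and 5 higher, and the list's median was -0.16. Mitochondrial ribosomal protein genes were then lower in 20 and higher in 6, with a median of -0.32 in place of -0.66. Oxidative phosphorylation genes were lower in 30 and higher in 1 (median -0.35 in place of -0.61), and proteasome genes lower in 16 (median -0.36 in place of -0.58).

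**Figure D2:**
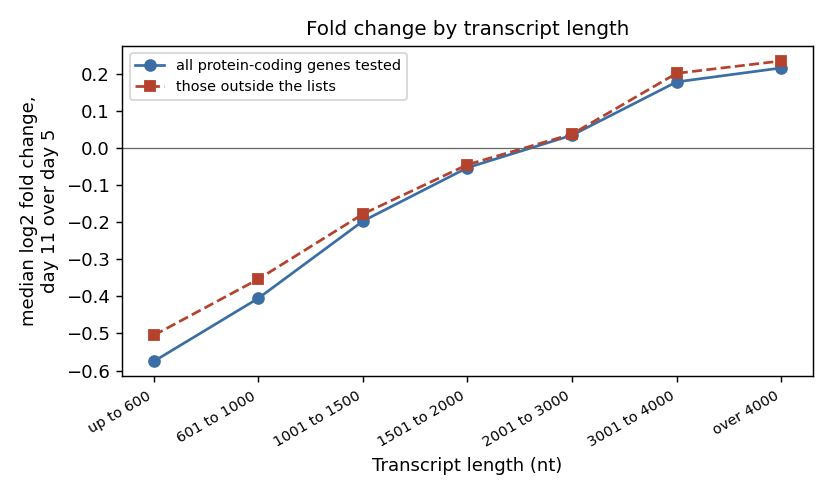
Median log2 fold change, day 11 over day 5, of tested protein-coding genes in 7 bins of transcript length in nt (circles), and of those outside the gene lists (squares). Outside the lists the median goes from -0.50 in the shortest bin to 0.23 in the longest.

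Genes of early eye development fell in part, and most of the tested genes of mature photoreceptors rose. Of 24 morphogenetic furrow genes, which act at the front of differentiation that crosses the eye disc, 8 fell and 1 rose, also when adjusted over the list alone (camera adjusted p = 0.00592; adjusted p = 0.671 with an estimated correlation). The proneural gene ato went from 31.2 ± 6.85 to 3.83 ± 1.75 CPM (SD, n = 3 each; edgeR log2 fold change -2.99, SE 0.31, adjusted p = 5.08e-05). Brd had -1.57, and lola rose by 0.91. With the transcript length trend removed, 13 morphogenetic furrow genes and 12 retinal determination genes were lower and 1 of each higher. Of 20 retinal determination genes 7 fell and 1 rose (8 and 1 when adjusted over the list alone; adjusted p = 0.0301, and adjusted p = 0.763 with an estimated correlation). dan had -1.78 and eya -1.49 (SE 0.20), and oc rose by 0.62, a call lost for oc in 1 of 17 other settings. Of 38 listed terminal photoreceptor genes 16 were tested. The count filter admits genes with enough counts on either day alone, and members low on both days were not tested. Of the 16 tested, 11 rose and none fell, also when adjusted over the list alone (median 1.98; adjusted p = 8.50e-06, and adjusted p = 0.248 with an estimated correlation). Pph13, a homeobox gene needed for rhabdomere formation, on chromosome 2L from 577486 to 579549, was near the counting floor at day 5 (0.0843 ± 0.146 CPM) and at 23.4 ± 2.94 CPM at day 11. The phototransduction G protein genes Ggamma30A and Gbeta76C rose by 2.81 (SE 0.19) and 4.06.

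Photoreceptor specification and neuronal genes rose in 14 and fell in 3 of 42, also when adjusted over the list alone (camera adjusted p = 0.0184, and adjusted p = 0.775 with an estimated correlation). The synaptic genes Syt1 and Snap25 rose by 2.32 and 3.35, and svp (-0.49) and Nrg (-0.35) fell. Cone and pigment cell genes rose in 10 and fell in 2 of 20, also when adjusted over the list alone. They were at the edge of the camera threshold (adjusted p = 0.0499, and adjusted p = 0.671 with an estimated correlation). sv rose by 2.96 and Pu by 1.53, while Ama (-0.66) and or (-0.74) fell. The calls of svp and or were each lost in 3 of 17 other settings and that of Nrg in 4. The call of Retinal determination was lost in 7 of 19 other settings. The call of Photoreceptor specification and neuronal genes was lost in 5 of 19 other settings, among them without day 11 replicate 1 (adjusted p = 0.306) and with the transcript length trend removed (adjusted p = 0.176). The median log2 fold change of this list, whose median transcript length was 3967.5 nt, was 0.246, and 0.0949 with the trend removed. The call of Cone and pigment cell genes was lost in 11 of 19 other settings.

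**Figure D3:**
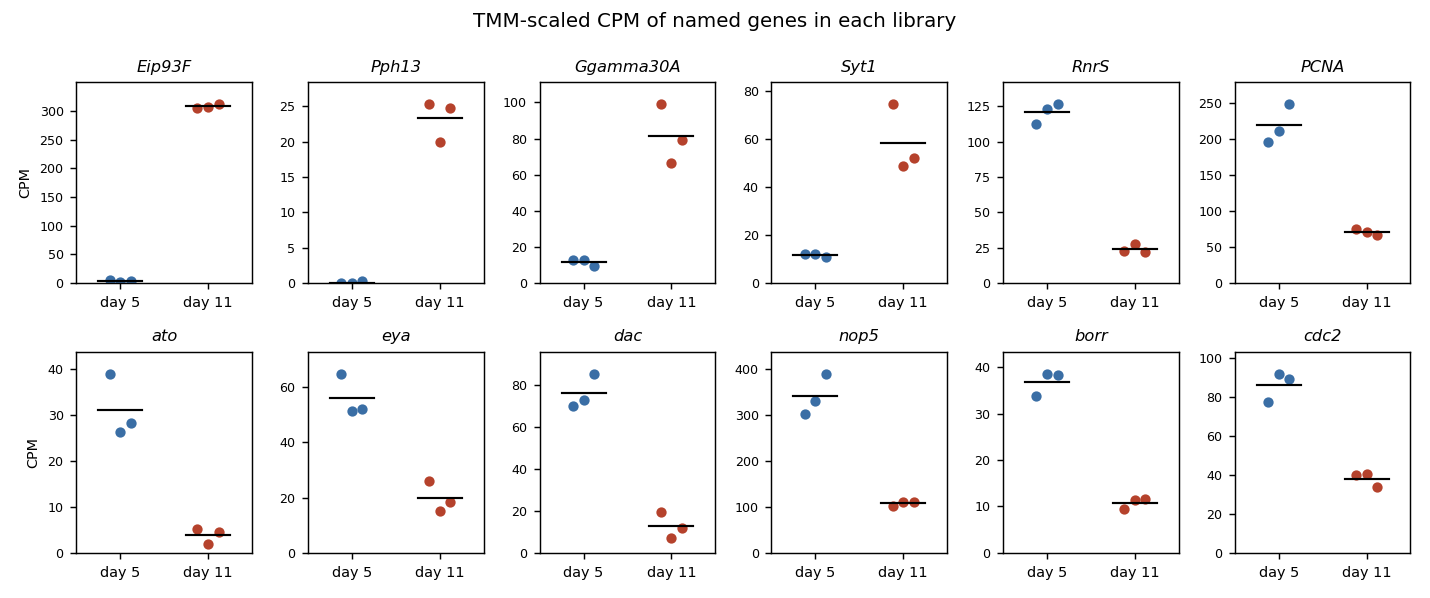
TMM-scaled CPM (linear axes from 0) of 12 named genes in each of the 3 day 5 libraries (blue) and 3 day 11 libraries (red), with the mean of each day as a bar. Eip93F, Pph13, Ggamma30A and Syt1 are higher at day 11 and the other 8 genes lower, with no overlap between the days.

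Lists of hormone-response, cuticle, lysosome and immune genes were called as higher at day 11, with part of their members rising. Of 30 ecdysone response genes, those known to answer the moulting hormone, 12 rose and 5 fell (13 and 5 when adjusted over the list alone; camera adjusted p = 0.0184, and adjusted p = 0.248 with an estimated correlation). The list's median log2 fold change was 0.37 and its mean 1.09. Its largest value, 8.79, was also the largest of the salivary gland, ring gland and gut list, which shares the salivary glue gene Sgs1 with it. The ecdysone and cuticle lists, as fixed, also share members. Besides Eip93F, the transporter gene E23 rose by a log2 fold change of 2.82 (SE 0.23), while Hr78 (-1.03) and Eip71CD (-1.33) fell. Eip71CD lost its call in 1 of 17 other settings. The call of Ecdysone response was lost in 4 of 19 other settings, among them without day 11 replicate 2 (adjusted p = 0.0617) and with the transcript length trend removed (adjusted p = 0.106). EcR, the hormone receptor gene, had a log2 fold change of 0.17 (SE 0.11) and was not called (edgeR adjusted p = 0.254). Of 159 listed cuticle and chitin genes 52 were tested. Of these, 24 rose and 6 fell (25 and 7 when adjusted over the list alone; adjusted p = 0.000176, and adjusted p = 0.240 with an estimated correlation). TwdlT rose by 4.19 and the chitinase gene Cht5 by 5.54, and Lcp65Ag1 (-2.78) and Cpr92A (-2.60) fell. Of 49 lysosome and autophagy genes 19 rose and none fell, also when adjusted over the list alone (adjusted p = 0.00041, and adjusted p = 0.274 with an estimated correlation). Among them were the proton pump subunit genes Vha100-2 (1.62) and Vha44 (1.05). Of 47 antimicrobial peptide and immune genes found in the counts 9 were tested. Of these, 6 rose, also when adjusted over the list alone (adjusted p = 0.0181, and adjusted p = 0.248 with an estimated correlation). The NF-κB gene Rel rose by 1.45, and Listericin went from 0.570 ± 0.605 to 14.4 ± 12.3 CPM. Its day 11 libraries held 28.6, 8.30 and 6.25 CPM, and its log2 fold change of 4.6 was 3.6 without day 11 replicate 1, with the call lost in 2 of 17 other settings. The call of Antimicrobial peptides and immune response was lost in 3 of 19 other settings.

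Transcripts of other cell types were present and varied between libraries. Haemocyte genes rose in 7 of 17 and fell in none (8 and 0 when adjusted over the list alone; adjusted p = 0.00349, and adjusted p = 0.671 with an estimated correlation). atilla rose by a log2 fold change of 2.80 (SE 0.25) and zfh1 by 1.17. The list's median CPM was 21.9, 54.7 and 44.6 in the day 11 libraries against 13.1, 17.4 and 19.7 at day 5. The lists of glial cells (adjusted p = 0.488), fat body (0.699), muscle and myoblasts (0.699), trachea (0.130), brain and neuroblasts (0.257) and salivary gland, ring gland and gut (0.232) were not called by camera. Single members changed. Among glial genes bnb (-1.48) and Gli (-0.84) fell, and bdl, listed as CG16857 (0.90), and pyr (1.15) rose, a call lost for pyr in 4 of 17 other settings. Obp99a (-0.70) fell in the fat body list, with adjusted p = 0.395 once the length trend was removed. In the muscle list Mef2 (0.91) and sns (0.96) rose and Mhc (-1.65) fell. The call of sns was lost in 6 of 17 other settings and that of Mhc in 4, and the log2 fold change of Mhc was -1.09 without day 5 replicate 2. In the trachea list serp (1.32) and obst-A (1.15) rose and bnl (-1.11) and knrl (-0.55) fell, the call of knrl being lost in 12 of 17 other settings. Rdl (1.91) and Syp (0.85) rose in the brain list, the call of Syp being lost in 1 of 17 other settings. The salivary glue gene Sgs4 was at 6.42, 7.38 and 56.8 CPM in the day 11 libraries and at 0.127 to 1.08 CPM at day 5 (log2 fold change 5.28, adjusted p = 0.0484), a call lost in 7 of 17 other settings. Fat body transcripts had a list median of 132.1 CPM in day 5 replicate 1 and 112.5 CPM in day 11 replicate 2, against 9.42 to 48.5 CPM in the other libraries.

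**Figure D4:**
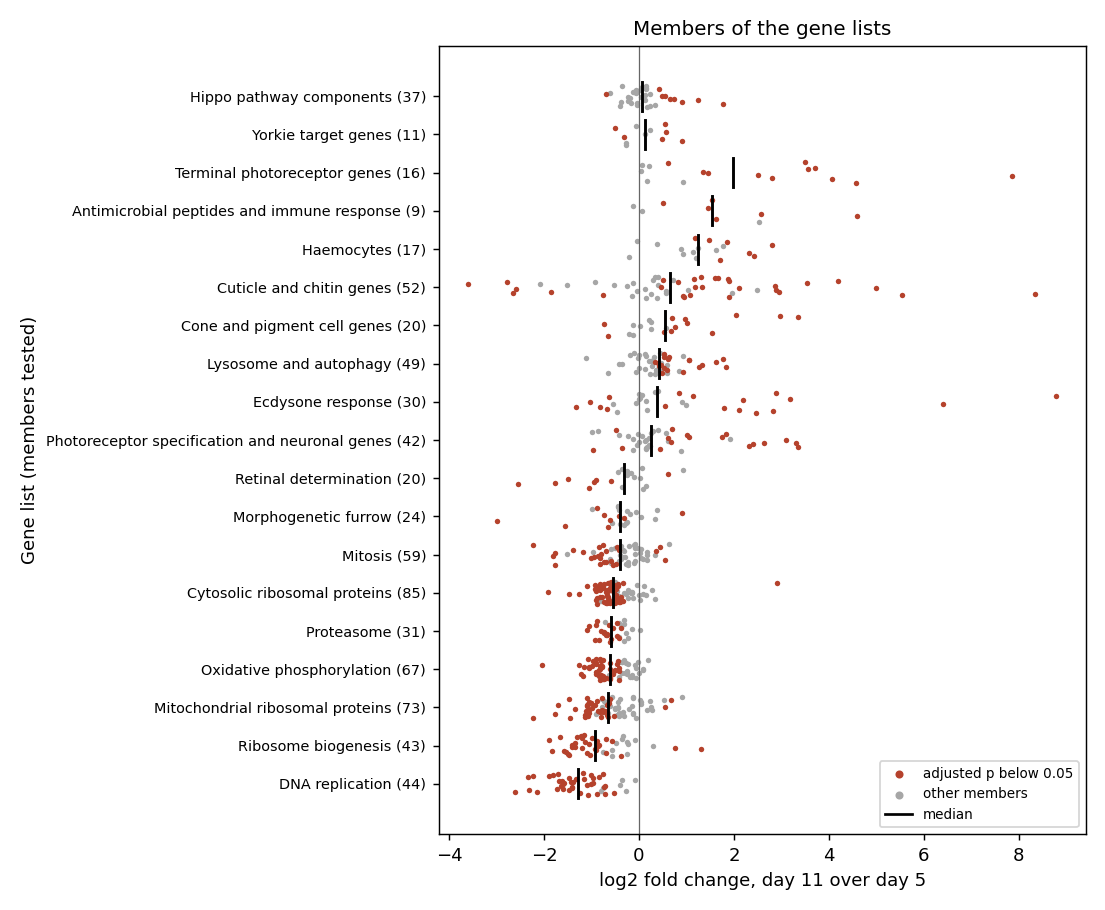
Log2 fold changes, day 11 over day 5, of tested members of the 17 gene lists called by camera and of the Yorkie target and Hippo pathway lists; red points have adjusted p below 0.05 and black bars are list medians. The DNA replication median is -1.29, the terminal photoreceptor median 1.98 and the Yorkie target median 0.12.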

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

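The removal of the transcript length trend and the omission of CR40469 and CR34335 were chosen after the data were seen; all other alternatives were fixed before. The number of changed genes, 2965, was 2202 to 3008 with a library left out and 2635 to 3139 in the other settings, and no gene called in the main and in another setting changed direction. Total-count scaling gave 865 higher and 2207 lower genes, 1079 of the genes lower by at least 2-fold in place of 534, and 3 called Yorkie target genes in place of 6; it omits the composition factor, which ranged from 0.850 to 1.16 between libraries. With a library left out, called Yorkie target genes numbered 3 to 7 and called Mitosis genes 14 to 26; fewer samples enter these fits. With an estimated correlation 0 lists were called, with adjusted p of 0.144 for DNA replication and 0.240 for Mitosis; in all other settings both stayed called, and the Yorkie target list was called in none (adjusted p 0.103 to 0.868). Among the other lists, Cone and pigment cell genes lost its call in 11 of 19 settings, Retinal determination in 7, Photoreceptor specification and neuronal genes in 5, Ecdysone response in 4, Antimicrobial peptides and immune response in 3 and Haemocytes in 2; the cause was not tested. Deviations of same-numbered libraries correlated at 0.0497, 0.194 and -0.0858, and those of different-numbered libraries at -0.230 to 0.166. These few values show no pairing by replicate number but cannot exclude it. With a replicate block 2940 genes were called, 1369 of them at least 2-fold, with 17 lists, 5 Yorkie target, 35 DNA replication and 27 Mitosis genes; of 100 named genes it ended the calls of dally and knrl. Depth limits genes near the floor, such as Pph13 at day 5.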

Other observations

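The tests of transcript length, photoreceptor share, brain carry-over and haemocyte carry-over were chosen after the data were seen; the counts over other splits of the libraries were planned before. Genes of nutrient signalling, named here after their values were seen, rose in 8 and fell in 3 of the 27 tested members of the insulin, TOR and FOXO list, which camera did not call (adjusted p = 0.0993; adjusted p = 0.536 with an estimated correlation) except on DESeq2 statistics (Insulin, TOR and FOXO, adjusted p = 0.00326). Thor, the translation repressor 4E-BP, went from 14.5 ± 0.876 to 280.8 ± 41.4 CPM (SD, n = 3 each; edgeR log2 fold change 4.27, adjusted p = 2.86e-08). Sesn (2.75), InR (1.14), S6k (1.02), REPTOR, listed as CG13624, (0.93) and REPTOR-BP, listed as CG18619, (1.73) rose, and mnd (-2.58) and srl (-0.69) fell. foxo itself had a log2 fold change of -0.07 and was not called.

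In 4 other lists, not called by camera in the main test, members named here were again chosen after their values were seen. JNK signalling and regeneration genes rose in 10 and fell in 4 of 26 (adjusted p = 0.316), with rises of puc (1.29) and kay (1.28) and a fall of bsk (-0.80); with the length trend removed 9 rose and 7 fell. Septate junction and cell adhesion genes fell in 9 and rose in 4 of 31 (adjusted p = 0.145), with falls of kune (-1.03) and sinu (-0.58) and rises of Cg25C (1.70), vkg (1.47), mys (0.55) and crb (0.49). Cg25C and vkg also stand in the haemocyte list, so their rises may not come from the disc's own cells. Septate junction and cell adhesion was called in 3 of 19 other settings, and with the length trend removed 14 members were lower and 1 higher (adjusted p = 0.0044). Antenna genes rose in 4 and fell in 5 of 21 (adjusted p = 0.476), with rises of bab1 (1.48) and bab2 (0.94) and a fall of rn (-1.82). Cell death genes rose in 5 of 16 and fell in none (adjusted p = 0.257), with rises of Dcp-1 (0.60) and of Iap2 (0.77), an inhibitor of cell death.

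The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. In 1 of the 10 splits, the real one, 2965 genes were called, and the highest of the others called 1; for changes of at least 2-fold 1 split reached the real 1366, and the highest other called 1. For lists, 1 split reached the real 17, but other splits called 9 to 16 lists, so list counts separate the real split far less than gene counts do. Each other split holds the days in unequal numbers, so part of the difference between the days stays in it. List calls there can come from that part, while the mixing of days within a group lowers its gene calls. These splits therefore do not show what would be called without a difference between the days.

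Genes with short transcripts had a lower median at day 11 also outside the lists, where 82 of 216 genes up to 600 nt fell and 28 rose, and a candidate explanation for the falls of ribosomal, respiratory and proteasome genes is a loss of short transcripts in the day 11 libraries. With the trend of genes outside the lists removed, the median log2 fold change was -0.16 for cytosolic ribosomal proteins (from -0.54), -0.32 for mitochondrial ribosomal proteins (from -0.66), -0.35 for oxidative phosphorylation (from -0.61) and -0.36 for the proteasome (from -0.58), against -0.93 for ribosome biogenesis (from -0.92) and -1.22 for DNA replication (from -1.29). All 6 lists stayed called at the preset correlation and their library medians did not overlap between the days. Neither sign weighs much: camera also called lists in splits that mix the days, and 10% of such comparisons do not overlap by chance. For ribosome biogenesis and DNA replication the medians hardly moved, which argues against the trend as the whole cause of their falls. For the other lists a part of the fall remained. By the rule set for this test, a list that stayed called, with its median still past a set limit, goes against the trend as its cause. All 6 lists met this rule, but it leans on the camera call at the preset correlation. For the other lists the values therefore do not decide whether the trend is the whole cause. With cytosolic ribosomal proteins most of the fall went with the trend, and the closest libraries were 0.00408 and 0.0637 from the list's mean. The slope of log2 CPM per doubling of length also varied within a day, from -0.131 to -0.0176 at day 5 and from -0.000566 to 0.201 at day 11. Whether the trend itself is technical, such as RNA quality, or a property of the older disc was not tested.

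The rise of terminal photoreceptor genes could come from a larger share of photoreceptor neurons, but elav, gl, fne, Rbp9 and Nrt, used by these neurons from their specification on, had a median log2 fold change of 0.151 and at most 0.166, below the terminal genes' lower quartile of 0.516. Their 95% intervals reached up to 0.43 for elav, 0.61 for fne, 0.91 for gl, 0.94 for Rbp9 and 1.23 for Nrt, so only that of elav stayed below 0.516. All stayed below the terminal genes' median of 1.98, which for these genes argues against a larger share as the whole cause of rises of that size. The genes were chosen after the data were seen, from the photoreceptor specification and neuronal list. In that list 14 of 42 tested genes rose and 3 fell, with Syt1 at 2.32 and Snap25 at 3.35. The argument therefore rests on the choice of genes. The day 11 libraries differed: replicate 1 held 241.1, 173.7 and 145.6 CPM of elav, gl and Nrt, replicate 2 held 133.4, 69.2 and 52.1, and replicate 3 held 151.3, 99.4 and 62.9. Brain tissue carried over in the dissection stays open: the 4 tested transmitter genes had a median of 0.216, but ChAT (listed as Cha), VAChT and Vmat had means below 3 CPM, too near the floor to exclude it. The fourth, nAChRalpha1, at a mean of 18.9 CPM, had a log2 fold change of 0.22 (95% interval -0.27 to 0.72). This interval reaches above 0.516, so the gene does not decide either. In the brain and neuroblast list 3 of 11 tested genes rose and 0 fell, among them Rdl (1.91, mean 14.8 CPM). Later differentiation of photoreceptors already present at day 5 is a hypothesis that remains untested apart from these values.

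Of 17 haemocyte genes 7 were called as higher at day 11 (Haemocytes, camera adjusted p = 0.00349, and adjusted p = 0.671 with an estimated correlation), and haemocytes carried over in the dissection are a candidate source. The median of Hml, NimC1, eater, Pxn and PPO2 was 5.35, 22.3 and 11.8 CPM in the day 11 libraries, a 4.17-fold range in which all 5 markers peaked in replicate 2, as uneven carry-over would give, though of these markers only NimC1 and eater passed between the days. At day 5 the medians differed by 1.42-fold, but single markers varied more, with PPO2 at 17.3 to 55.0, NimC1 at 1.57 to 3.92 and Hml at 10.5 to 22.8 CPM, so the values do not decide between carry-over and more haemocytes on the older disc.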
